A study of Pimephales promelas with 10 samples.

How the data were processed

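Gene expression was measured in whole testes of adult male fathead minnows (Pimephales promelas) after a 21 day exposure to the explosive formulation IMX-101 or to clean water. Per the labels' protocols, each of the 5 tanks of a treatment held 2 fish in 6.0 L of test solution at 23 °C, and 3.0 L of the solution was renewed at each change. One replicate is the testis RNA of 1 tank. RNA of both fish was pooled where both extracts passed the quality criteria, which included an RNA integrity number above 8.0, and otherwise came from 1 fish; which case applies to a given replicate is not given in the sources used here. The groups were taken from the sample titles: 5 control arrays (0 mg/L) and 5 arrays at 12.6 mg/L. The other concentrations named in the labels were not analysed here.

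Per the labels' protocols, 80 ng of total RNA per replicate was labelled with a single dye (Cy3) and hybridised to an Agilent one-colour array. Per the file headers and the submitters' processing notes, the scans were read with Agilent Feature Extraction 10.7.3.1. The deposited intensity used here is the processed spot signal, which per the file headers is on a linear scale, has the local background and a spatial trend subtracted, and has very low values replaced by a small positive stand-in. The authors also deposited a table of processed values. Its scale and scaling are not stated. Set against the scanner values of the same arrays, each of its columns followed log2 intensity minus the array's 75th percentile, with every probe centred on its median over the 10 arrays (Pearson correlation across probes of at least 0.999 for every array). Its values are thus log2 differences from the authors' probe median and hold no absolute level. The medians of its columns were -0.15, 0.0019, -0.14, 0.077 and 0.18 for exposed replicates 1 to 5, and 0.037, 0.037, -0.022, 0.022 and -0.024 for control replicates 1 to 5.

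From the scanner files, control spots and spots flagged as outliers (131 to 281 per array) were left out, and no gene spot was saturated. The remaining signals were put on the log2 scale, the 75th percentile of the array was subtracted, and spots of the same probe were averaged. Each level given is therefore relative to the 75th percentile of its own array. A probe was tested if it was well above background on at least 3 arrays of either group, which kept 43084 of 49849 probes. Exposed and control arrays were compared with limma 3.58.1 (lmFit and eBayes, group as the only term) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all tested probes, and a probe was called at an adjusted p under 0.05. Intervals are 95% intervals of this model. Whether arrays of a group resembled each other more than arrays of the other group was tested with the mean Pearson correlation within groups minus that between groups, on probe-centred values, in an exact one-sided permutation test over all assignments of the arrays to groups of 5. A probe that was not well above background on any control array has only an upper bound there; its fold is given as "at least", against the higher of its own signal and the lowest signal of any probe well above background on each control array. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

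The files do not pair the probe names with genes, and 0 of the 49849 probe names occurred in the RefSeq gene table used here. The 31 gene lists fixed before the data were examined (testis cell types, steroid production, toxicant responses, energy metabolism and other cell types) could therefore not be tested, and no gene could be named. The naming rule, also fixed before the data were examined, was to name genes by symbol: those called with non-overlapping groups and the largest change, filled up with the smallest unadjusted p, plus members of the gene lists and a set of steroid and hormone receptor genes. It was carried over to probe identifiers after the data were seen. All called probes are named, together with the lower-level probes with the 2 smallest p-values, which were not called. The filling up was not carried over for higher probes, although some that were not called had smaller p-values than these. A pair of such higher probes, chosen after the values were seen, is given beside them.

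The arrays came from 3 slides, each scanned on its own occasion. Slide 1 held control replicates 1, 2 and 3 and exposed replicate 1. Slide 2 held control replicates 4 and 5 and exposed replicates 2 and 3. Slide 3 held exposed replicates 4 and 5. Slide was not a term of the model but was tried as a fixed block, as a random block and within slides. Other alternatives were other call thresholds, other scalings, the authors' table, other filters and outlier spots kept. Further ones were other variance settings, array weights, the replicate number as a block, and each array left out in turn. Normexp background correction was run on the median spot signal, with an offset of 50 added to every corrected intensity. The mean signal that had been planned is not among the columns of the files. This version, a common floor for all arrays, and the comparison without slide 3 and with no block were added after seeing the data; the one without slide 3 and with slide as a block was planned.

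The model was tested on simulated data with the exposed and control arrays' own levels and spread. In 5 simulations of 43037 probes with 200 changed probes, 23% of the probes changed by 2-fold were called, 62.7% of those changed by 4-fold and 90.9% of those changed by 8-fold, with a mean of 7 false calls. With no changed probe there were 0 calls and 5.07% of probes had an unadjusted p under 0.05. The number of arrays, 5 per group, limits the precision.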

Results

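The study asked how IMX-101 affects the reproductive physiology of male fathead minnows, a small North American fish widely used in aquatic toxicology. IMX-101 is an insensitive munition, a melt-cast explosive made to resist accidental detonation, and contains dinitroanisole (DNAN), nitrotriazolone (NTO) and nitroguanidine (NQ). Per the study's design text, the nominal value was used for DNAN in stating the concentration, because little of the compound was measured in the water. Testes of 5 control tanks and of 5 tanks at 12.6 mg/L, sampled after 21 days, were each hybridised to 1 array with 49849 gene probes in 61053 spots. The design text calls the tanks replicates, so the spread below is that between tanks, each with the RNA of 1 or 2 fish.

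The probes carry contig and clone names of the fathead minnow array and could not be paired with genes, so the account below is in probes.

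Signal over background was similar on 9 of the 10 arrays. Between 81.4% (control replicate 5) and 86.5% (control replicate 4) of the gene spots were well above background on them, against 40.3% for exposed replicate 5. The lowest processed intensity was 38.8 on that array and between 2.26 and 3.47 on the others, so that dimmer probes had no measured level there. The 75th percentile of intensity ran from 480 (exposed replicate 4) and 538 (exposed replicate 2) to 962 (exposed replicate 1), and from 642 to 893 on the control arrays. The brightest spike-in control, an RNA added in a fixed amount during labelling, lay 8.55 and 7.95 log2 units above the 75th percentile on the arrays of exposed replicates 4 and 2, and between 6.34 and 7.22 log2 units above it on the control arrays. Spots of a probe printed 10 times had a median SD of 0.103 to 0.145 log2 units on 9 arrays and of 0.198 on that of exposed replicate 5.

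**Figure D1:**
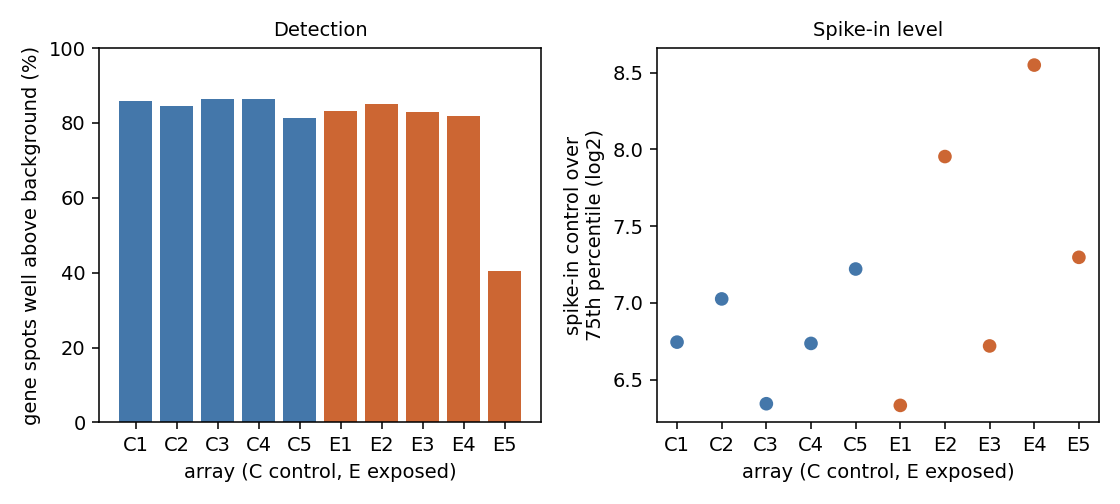
Left, percent of gene spots well above background on each array (bars, from 0). Right, log2 level of the brightest spike-in control over the array's 75th percentile (points, 1 per array). C, control; E, exposed to 12.6 mg/L; numbers are replicates. Exposed replicate 5 has 40.3% of spots well above background, and exposed replicates 2 and 4 have the highest spike-in levels.

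The signal of 3 probes differed between exposed and control testes, and each was higher after exposure. SINGLET_7367 had a log2 level of -7.77 ± 0.47 (SD, n = 5) in control and -2.40 ± 1.3 (SD, n = 5) in exposed testes, a log2 change of 5.37 with SE 0.54 (95% interval 4.17 to 6.56, limma adjusted p = 0.027). It was not well above background on any control array and was so on 4 of 5 exposed arrays, and with the scanner software's background correction it was at least 22-fold higher. CONTIG5561 had a log2 level of -6.81 ± 0.52 in control and -3.91 ± 0.35 in exposed testes (SD, n = 5 each), a log2 change of 2.89 with SE 0.27 (95% interval 2.29 to 3.50, limma adjusted p = 0.027). It was well above background on no control array and on 3 of 5 exposed arrays, and with the same background correction was at least 6.71-fold higher. Both bounds use the mean over all 5 exposed arrays, including those where the probe was not well above background. SINGLET_45763 had a log2 level of -5.85 ± 0.33 in control and -3.33 ± 0.55 in exposed testes (SD, n = 5 each), a log2 change of 2.51 with SE 0.28 (limma adjusted p = 0.0452), and was well above background on 1 control and 4 exposed arrays. For each of the 3 probes all 5 exposed values lay above all 5 control values. With slide as a fixed block the log2 changes of SINGLET_7367, CONTIG5561 and SINGLET_45763 were 5.66, 2.99 and 2.66, each with an adjusted p of 0.16. These estimates rest on the arrays of slides 1 and 2, because slide 3 holds exposed arrays alone. Within slide 2, with 2 arrays of each group, the log2 changes were 5.05, 2.73 and 3.03 (adjusted p = 0.759 each), and within slide 1, with 1 exposed and 3 control arrays, 6.48, 3.34 and 2.17 (adjusted p = 0.105, 0.237 and 0.238). With any one of 6 arrays left out (exposed replicate 1 or 5, control replicate 1, 3, 4 or 5) limma called 0 probes (2949 to 5312 at an unadjusted p under 0.05), although over all arrays left out in turn the log2 changes stayed between 4.95 and 5.73, 2.68 and 3.04, and 2.29 and 2.66. Quantile normalization ended the 3 calls too, with log2 changes of 4.92, 2.50 and 2.13 (adjusted p = 0.0954, 0.403 and 0.403). The 3 calls are of dim probes, and their changes were smaller in runs that treat low signals otherwise. The bounds above therefore do not hold under other treatments. The log2 changes were 2.00, 0.69 and 1.07 with normexp background correction, with 0 probes called by limma (2702 at an unadjusted p under 0.05). With all values raised to the floor of exposed replicate 5 they were 1.87, 0.409 and 0.945, again with 0 probes called (4054 at an unadjusted p under 0.05). Normexp added an offset of 50 to every spot, and the floor of -4.279 lay above every control value of the 3 probes. Both steps shrink changes of dim probes by construction, so these runs do not show what background correction alone does.

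No probe was called lower by limma, although 2631 were lower at an unadjusted p under 0.05. The probes with the smallest p-values on that side were CONTIG3997, at -1.87 ± 0.16 in control and -3.33 ± 0.51 in exposed testes (log2 change -1.46, SE 0.24, limma adjusted p = 0.369), and CONTIG2873, at -1.13 ± 0.15 and -2.01 ± 0.17 (log2 change -0.88, SE 0.15, limma adjusted p = 0.369; SD, n = 5 per group). All 5 exposed values of both lay below all 5 control values, without passing the correction for 43084 tests. Some higher probes that were not called had smaller p-values than these. SINGLET_29859 had a log2 change of 2.91 (SE 0.44) and UF_Ppr_AF_108611 of 2.76 (SE 0.45), each with a limma adjusted p of 0.369. Both were well above background on all 5 control arrays, and their groups did not overlap. Their levels correlated at 0.998 over the arrays, so they may not be separate signals.

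**Figure D2:**
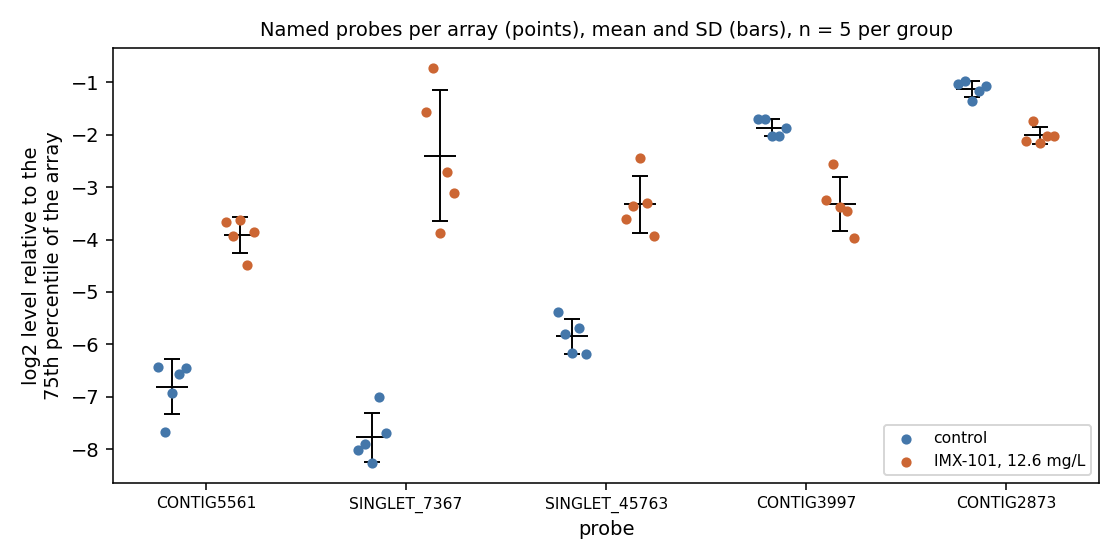
Log2 level of 5 probes relative to the 75th percentile of each array, on the y axis. Points are single arrays, bars the mean and SD of 5 arrays per group. The 3 probes on the left were called higher in exposed testes, while the adjusted p of the 2 on the right was 0.369.

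Below the threshold, lower probes outnumbered higher ones. At an unadjusted p under 0.05 there were 3764 probes, 8.74% of those tested against 5% by chance, of which 2631 were lower and 1133 higher in exposed testes (69.9% lower). Among the 19331 probes well above background on all 10 arrays, 948 of 1265 such probes were lower. All values of one group lay outside the range of the other for 947 lower and 141 higher probes, 2.53% of those tested where chance gives 0.794% for a single probe; probes are not independent, and 3 of 100 splits of the arrays gave as many, the real one included (highest other 1184, median of the others 270). The lower share depended on the processing and on 1 array. It was 53.3% with normexp on the median spot signals, a run that replaces the signal and its background correction and adds an offset of 50. It was 81.4% with the common floor and 54.9% (2914 lower and 2398 higher) without exposed replicate 1. With slide as a fixed block it was 68.5%. Within slide 2 it was 47.5%, and within slide 1, where exposed replicate 1 is the only exposed array, 74.1%. Across all tested probes the median log2 change was -0.027, against -0.094 with quantile normalization and 0.057 with normexp.

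For most probes the model with group as its only term bounded the size of a change. These bounds hold for that model and the scanner software's background correction, and not for other treatments of slide or background. The median SE of a log2 change was 0.281, and for 25171 probes (58.4%) the 95% interval lay wholly within a 2-fold change in either direction. It lay within a 4-fold change for 91.3% of the tested probes. Among probes well above background on all 10 arrays, the interval lay within 2-fold for 76.0%. Estimates of at least 2-fold were higher for 1728 probes and lower for 306. These counts include dim probes. The lowest log2 level was -4.279 on the array of exposed replicate 5 and between -8.465 and -7.112 on the others, which lifts the exposed mean of dim probes. How much of the excess of higher estimates comes from this floor was not tested. In the simulated data, with equal spread in both groups and no slide effect, 23% of 2-fold changes and 90.9% of 8-fold changes were called. A change of 2-fold in a single probe was thus mostly not detectable with these arrays.

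As whole profiles, arrays of a group were not shown to resemble each other more than arrays of the other group. The mean correlation of probe-centred values was 0.0904 higher within than between groups, and in an exact one-sided permutation test over all assignments of the arrays this gave p = 0.0873. Within slide 2 the difference was 0.0986 (exact p = 0.333 over 6 assignments, the smallest possible with 2 arrays per group), and within slide 1 it was 0.174 (exact p = 0.25, the smallest possible with 4 arrays). The rank correlation across probes averaged 0.949 over the 10 pairs of control arrays (0.931 to 0.960), 0.906 over the 10 pairs of exposed arrays (0.869 to 0.942) and 0.922 over the 25 pairs between groups. Probes are not independent replicates, so these correlations carry no p-value.

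The spread between arrays was wider in the exposed than in the control group. The median SD of a probe was 0.509 log2 units between exposed arrays and 0.331 between control arrays, a ratio of 1.54, and the SD was larger in the exposed group for 73.8% of probes. In an exact two-sided permutation test over all assignments the ratio gave p = 0.0159. Slide 3 held exposed arrays alone. With the 3 exposed arrays of slides 1 and 2 the ratio was 1.35, and in reassignments within these slides 2 of 24 ratios lay as far from 1, the real one included. Within slide 2, where there are 2 arrays per group, it was 1.29, with no test.

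**Figure D3:**
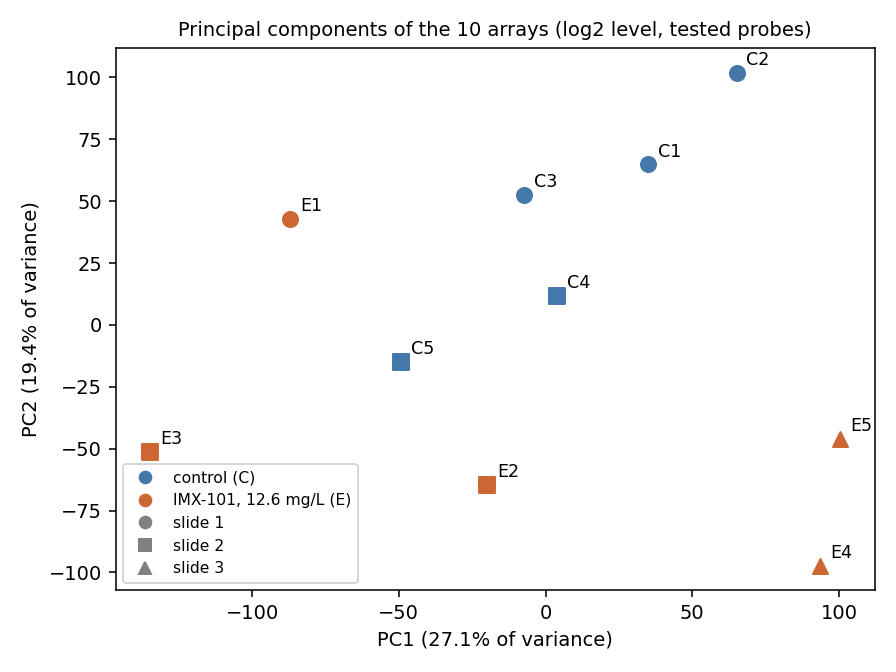
First and second principal components of the log2 levels of the tested probes, with 27.1% and 19.4% of the variance on the axes. Each point is 1 array (C, control; E, exposed; the number is the replicate), colour gives the group and symbol the slide. The 2 arrays of slide 3, both exposed, lie together at the right, apart from the other exposed arrays.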

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

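Of the tests given here, those of the raised floor, of slide, of slide 3, of the scaling, of the low signal of replicates 2 and 4, of the background correction and of the spread within slides were chosen after the values they use, or closely related ones, had been seen.

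Among 26 groups of 5 values checked (array quality values, correlations and the probes named), a single value stood far from the rest of its group, about as many as the 1 in 20 that chance gives. On the array of exposed replicate 5, 40.32% of gene spots were well above background, while the other 4 exposed arrays had 81.95% to 85.09%. The lowest processed intensity, which was not among the values checked, was also apart on that array: 38.8 against 2.26 to 3.47 on the others. The number of flags is therefore no reason to take this value for chance.

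The first pattern is the 3 probes called higher: a raised floor on the array of exposed replicate 5 would lift dim probes there, but without that array the smallest log2 change of the 3 was 2.66. Within slide 2 the smallest log2 change of the 3 was 2.73, which a level difference between slides cannot give. The 3 probes were chosen on arrays that include these, however, so this is no independent test of slide. A general lift of dim signals on the exposed arrays is argued against by the 4188 probes not well above background on any control array. For the exposed arrays of slides 1 and 2 their median log2 change was 0.081 (5th to 95th percentile -0.565 to 1.04). Single dim probes did change more, with a log2 change of at least 2 for 44 of them. Of 100 splits of the 10 arrays into 5 and 5, drawn from all splits, 3 gave 3 or more called probes, the real split included. Of the 24 assignments that move arrays only within slides 1 and 2, only the real one, 1 of 24, did (highest other 1). That is the smallest share these can give, so chance is made less likely for the fit without a block but is not excluded. The highest of the other splits called 21, several times the real count. It sets slide 2 with exposed replicate 1 against the rest, which points to a structure of the arrays. With slide as a fixed block, slide 3 adds nothing to the estimated change, because it holds exposed arrays alone. The log2 changes of SINGLET_7367, CONTIG5561 and SINGLET_45763 then went from 5.37 (SE 0.54), 2.89 (SE 0.27) and 2.51 (SE 0.28) to 5.66 (SE 0.66), 2.99 (SE 0.32) and 2.66 (SE 0.33). The calls ended as the SE grew and the degrees of freedom fell from 10.4 to 8.6. A response of these probes to the exposure is therefore a hypothesis, which rests on signals near the background.

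The second pattern is the wider spread among exposed arrays. Among 100 splits 2 gave a ratio of median SDs as far from 1 as the real 1.54, the real split included, and the highest other gave 1.56, but these splits mix slides; over slides 1 and 2, with arrays moved only within a slide, 2 of 24 ratios lay as far from 1 as the real 1.35 (the real one, and 1 below 1 at 0.728), so chance is not excluded there. Without exposed replicate 5 the ratio was 1.47, and 1.33 to 1.62 with a further array left out, which argues against that array as the whole source. Slide 3, which holds exposed arrays alone, stays open, because with the exposed arrays of slides 1 and 2 the ratio was 1.35 but fell to 1.16 with 1 more array left out. Noise of dim probes stays open too, since the ratio was 1.34 over probes well above background on all arrays, with 1.21 to 1.41 when an array was left out. A different response of the tanks to the exposure was not tested. Neither was the number of fish per replicate, 1 or 2, which is not known for each array.

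The third pattern is the excess of lower probes at an unadjusted p under 0.05. Scaling is argued against, since the lower share was 64.3% or more under quantile normalization and median centring, and so is the low signal of exposed replicates 2 and 4, without which it was 79.6%. Background correction stays open. The share was 53.3% with normexp, but that run also replaced the processed by the median signal and added an offset of 50. It was 81.4% with the common floor. The array of exposed replicate 1, without which the share was 54.9%, stays open too. Chance cannot be excluded as the source of the excess of small p-values: 8 of 100 splits gave 3764 or more such probes, the real split included, and the highest other gave 5005; the share on the commoner side was as large in 35 of the 100, and up to 87.2%. The lower share within slide 2 was 47.5%, and an effect of the exposure on these probes was not separated from these.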

How the results depend on the processing

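Normexp on the median signals, the common floor and the comparison of slides 1 and 2 with no block were chosen after seeing the data; the other alternatives were listed before the data were examined. No alternative called a lower probe and the 3 called probes stayed higher in each of their 26 fits, but the number called by limma was not stable. It was 0 with quantile normalization (4042 probes at an unadjusted p under 0.05), with only probes well above background on all arrays (1654), for slides 1 and 2 with slide as a block (4637) and with no block (4774), within slide 1 (6238) and within slide 2 (2432), with normexp (2702) and with the common floor (4054). It was 1 with median centring, 1 with the trended and robust variance and 1 with slide as a fixed block, where the probe was not among the 3. The fixed block gives the same log2 changes as slides 1 and 2 with slide as a block, so these are not separate estimates. The number called was 2 with no filter. It was 3 at an adjusted p under 0.10 and with a change of at least 1.5-fold required, but these settings could not drop any of the 3. The authors' table and outlier spots kept also gave 3, on nearly the same values as the main fit. Array weights and slide as a random block gave 3 as well. With 1 array left out it ranged from 0 to 2: 0 without exposed replicate 1 or 5 or control replicate 1, 3, 4 or 5, 1 without exposed replicate 4 or control replicate 2, and 2 without exposed replicate 2 (1 of them among the 3) or 3. The log2 changes of SINGLET_7367, CONTIG5561 and SINGLET_45763 stayed between 4.95 and 5.73, 2.68 and 3.04, and 2.29 and 2.66 in these fits. The fit on bright probes holds none of the 3, and those within slides have 1 or 2 exposed arrays, so their counts say nothing of the 3. Fewer arrays or probes were used in the fits within slides, without arrays and on bright probes; for the other settings the cause was not tested. With the replicate number as a block, 0 probes were called (3436 at an unadjusted p under 0.05). Same-numbered arrays correlated at 0.031, -0.093, 0.080, 0.015 and -0.29, and 0 of 5 control arrays matched best with their own number. No pairing by number was thus seen. It is not excluded, because same-numbered arrays share a slide only for replicate 1 and slides differ. The share of lower probes at an unadjusted p under 0.05 stayed above 50% in 26 of 27 alternatives, up to 81.4% with the common floor, and was 47.5% within slide 2; without exposed replicate 1 it was 54.9%. The separation of the arrays did not reach an exact p under 0.05 in any of 22 alternatives (p = 0.0556 to 0.333). It was not run for the settings that alter only the model (variance, weights, slide blocks). Within slide 1, within slide 2 and with the replicate number as a block, too few distinct assignments exist for an exact p under 0.05. These settings therefore say nothing for or against a separation. Normexp on mean signals and all tests of gene lists were not run. Signal over background limits the 3 called probes: none was well above background on all exposed arrays.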

Other observations

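The probes could not be paired with genes here, so these observations are of probes and arrays; they were chosen after the values were seen.

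Some exposed arrays had many probes far above all other arrays. Probes well above background and at least 8-fold above every other array numbered 50 on the array of exposed replicate 3, 28 on that of exposed replicate 5, 24 on that of exposed replicate 4, 2 each on those of exposed replicates 1 and 2, and between 0 and 2 on the control arrays. The 50 probes of exposed replicate 3 had a median log2 level of 3.27 there, far above the 75th percentile of the array, and of -2.83 over the control arrays. For 13 of the 50 the next highest array was exposed replicate 1. The next highest array was the other array of slide 3 for 11 of the 24 probes of exposed replicate 4 and for 8 of the 28 of exposed replicate 5. Whether these probes follow the slide was not tested.

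Some probes had widely separated high and low levels. On the 9 arrays other than that of exposed replicate 5, 43 probes split the arrays by a gap of at least 32-fold. They followed 28 different patterns of arrays, with at most 5 probes on 1 pattern. None of the 43 parted exposed from control arrays, and 36 had arrays above and below the gap in both groups. Whether the low levels lay within background was not checked. How many of each kind chance would give was not worked out, so these counts say nothing for or against an effect of the exposure.

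Slides differed in level for many probes. With group and slide in 1 limma model, 53 probes differed between slides 2 and 1 at an adjusted p under 0.05 (6 higher and 47 lower on slide 2) and 964 between slides 3 and 1 (922 higher and 42 lower on slide 3). The slide 3 value includes any difference between its exposed arrays and those of the other slides, and the raised floor of exposed replicate 5.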
